A study of Mus musculus with 9 samples.

How the data were processed

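The samples were laser-captured epithelial lesions from formalin-fixed, paraffin-embedded prostates of 12-month-old male mice of mixed strain background. Per the labels' protocols, a pathologist's reading of stained serial sections guided the capture, RNA was extracted with a kit for fixed tissue, amplified and labelled with a NuGEN Ovation system, and hybridised to the Affymetrix Mouse Gene 2.0 ST array, with 1 channel and 1 array per capture. RNA from fixed tissue is fragmented and amplified from small amounts, which can lower the signal and widen the spread between arrays. The deposited values are intensity values on a linear scale for 41345 probe sets, between 1.36 and 13922, with close but not identical distributions on the 9 arrays (medians from 13.6 to 15.4). Background correction, probe summary and between-array normalization by the authors are not given in the sources used here, so part of a change may depend on unknown upstream scaling. No depth exists for arrays; their number, 3 per group, limits the precision.

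Control means mice without the T-3Mb-Erg allele. Groups were taken from genotype, lesion and mouse in the labels: 3 control HG-PIN arrays, 3 T-3Mb-Erg HG-PIN arrays and 3 T-3Mb-Erg tumour arrays. Arrays of a group came from separate mice. The replicate numbers of the latter groups mark the same mice, as the labels' mouse identifiers say, so the mouse entered the fit as a random block. The correlation of same-mouse deviations from the group means was 0.17, 0.10 and -0.30, and the fit was in effect close to an unpaired one. A fit with the mouse as a fixed block is given beside it. All comparisons, gene lists, the rule for named genes and all alternatives except 2 were fixed before the data were examined. The 2 added later were a fit without the array of each group with the lowest 95th percentile of log2 signal, and a fit with that percentile as a numeric term.

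Probe sets were named through the platform annotation given with the series, updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6; the build behind the annotation is not stated and no coordinates are printed. Exactly 1 symbol was listed for 23521 probe sets (23328 with a matching identifier), several for 1814, and none for 16010; probe sets of the latter kinds were not named. The brightest probe set by mean over 9 arrays was kept for each of 22180 symbols, which mattered for 1082 symbols with more than 1. Values were log2-transformed without a pseudocount (floor 1, reached by 0 values), and genes in the lowest 25% of mean signal (mean log2 below 3.25) were removed, leaving 16635.

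Differences were fitted with limma 3.58.1 in R 4.3.3: group means over all 9 arrays, the mouse as a random block through duplicateCorrelation (consensus correlation -0.01), and empirical Bayes variances with a mean trend. Log2 changes are given with SE, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called; adjusted p values in the text come from this fit or, for lists, from limma's cameraPR adjusted over the 37 lists of a comparison. cameraPR compares a list's moderated statistics with those of all other genes with a preset correlation of 0.01; it was repeated with a correlation estimated for each list, and fry was run on the same lists. fry tests whether the genes of a list move on balance in 1 direction, and called 0, 2 and 3 lists in the 3 comparisons. A count adjusted over the list alone applies the same adjustment to the p values of its members. The lists held interstitial and engineered genes, epithelial lineages, prostate and seminal vesicle secretions, markers of stromal, vascular, nerve, muscle, fat and blood cells, and signalling, stress, metabolic and growth pathways. Overlap was counted only among the luminal, basal, transition, fibroblast, matrix, TGF-beta, ERG-associated, smooth muscle, interferon, interstitial and endothelial lists. There, 1 tested member each was shared by transition and TGF-beta, transition and ERG-associated, fibroblast and matrix, and ERG-associated and endothelial lists. The matrix and ERG-associated lists shared 2, as did the interstitial and interferon lists. Other pairs overlap too, such as the fibroblast and T and NK cell lists (Thy1) and the engineered and androgen response lists (Tmprss2).

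Named genes were, for each comparison and direction, the 10 largest changes among called genes that moved the same way in every mouse or did not overlap between groups, without symbols of predicted models, microRNAs and small nucleolar RNAs of the Snor form (AF357399, a small nucleolar RNA under another symbol, was not excluded by this); the 5 with the smallest p where fewer than 5 were called; every interstitial gene with Erg and Tmprss2; up to 4 called members of each list, or else 2 with the smallest p; and for tumours against HG-PIN a set of keratins, Vim, Cdh1, Epcam and Mki67. Interstitial genes are those of the preset list, which left out Itgb2l although it lies between Tmprss2 and Erg in the RefSeq genes used. Further list members that pass when adjusted over the list alone were added as examples after their values were seen. Krt5 had no probe set with a single symbol of its own in the annotation and was not analysed here.

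Alternatives were a stricter and no signal filter, no block, a fixed block, only the arrays of the compared groups, quantile normalization, median centring, array weights, other variance priors, the mean of probe sets, a threshold of 0.10 and leaving out each array in turn. The fits were tested on simulated data with the real means and moderated spreads, and with noise drawn independently for each gene and array. Of 50 genes changed by 1 log2 unit, 28% were called in the genotype comparison and 24% in the tumour comparison, and of 50 changed by 2 units, 100% and 96%. A permutation test of arrays was run in scipy 1.17.1 with Python 3.11.15, and figures were drawn with matplotlib 3.10.9.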

Results

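Gene expression was measured in prostate epithelium of 12-month-old male mice by laser capture of defined lesions from fixed sections and hybridisation of the amplified RNA to 9 mouse whole-transcript arrays. Of the 2 genotypes, 1 carried the T-3Mb-Erg allele on a single chromosome and the other, called control here, did not. What else the mice of both genotypes carried is not described here, and the lesions of control mice are not normal tissue. There were 3 groups of 3 arrays each: high-grade prostatic intraepithelial neoplasia (HG-PIN, a lesion of dysplastic cells within the gland) from control mice, HG-PIN from T-3Mb-Erg mice, and poorly differentiated adenocarcinoma from T-3Mb-Erg mice. The tumour and HG-PIN captures of the T-3Mb-Erg genotype came from the same 3 mice and share their replicate numbers, so the arrays represented 6 mice in all. The number of arrays limits the precision: the 95% interval of a gene's log2 change had a median half-width of 0.59 between HG-PIN of the 2 genotypes. The spread of signal within an array differed from array to array. Its 95th percentile of log2 intensity lay between 5.61 and 5.95 in control HG-PIN, between 5.78 and 6.16 in T-3Mb-Erg HG-PIN and between 5.63 and 6.25 in tumours. The first principal component, which held 32.9% of the variance, followed this range across arrays (Pearson's r = -0.98, Spearman's rank correlation -1, n = 9, exact permutation p = 5.51e-06 for both, the smallest the permutations can give; r = -0.96 without the 2 farthest arrays).

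The first comparison set HG-PIN of T-3Mb-Erg mice against HG-PIN of control mice, and addressed what the added allele changes at the same lesion, with the genes between Tmprss2 and Erg as its first subject. None of the 14 interstitial genes tested passed the threshold, and their changes lay on both sides of 0. Positive log2 changes were found for Pcp4 (0.80), Hmgn1, a nucleosome-binding protein (0.60), Lca5l (0.36), B3galt5 (0.34), Mx1 (0.20), Get1 (0.13), Bace2 (0.09) and Psmg1 (0.02). Negative changes were found for Fam3b (-0.21), Igsf5 (-0.20), Dscam (-0.14), Ets2, an ETS-family transcription factor (-0.14), Brwd1 (-0.12) and Mx2 (-0.04). The median of the list was 0.05 (adjusted p = 0.548; adjusted p = 0.930 with an estimated correlation), and no member passed when adjusted over the list alone. Ets2 stood at 5.26 ± 0.43 in T-3Mb-Erg HG-PIN and 5.40 ± 0.46 in control HG-PIN on the log2 scale (SD, n = 3 each). The 95% interval of that change ran from -1.18 to 0.91. The interval of 12 of the 14 genes lay above -1, which corresponds to a 2-fold lower signal. Only 3 of the 14, Ets2, Pcp4 and Bace2, had a mean above 4.80, the 95th percentile of 1394 olfactory and vomeronasal receptor genes taken as a gauge of background. A lower transcript level of the others was not detectable with confidence. Sh3bgr lay below the signal filter and was not tested (3.13 ± 0.28 and 3.19 ± 0.40). Itgb2l, also between Tmprss2 and Erg, was not in the preset list.

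**Figure D1:**
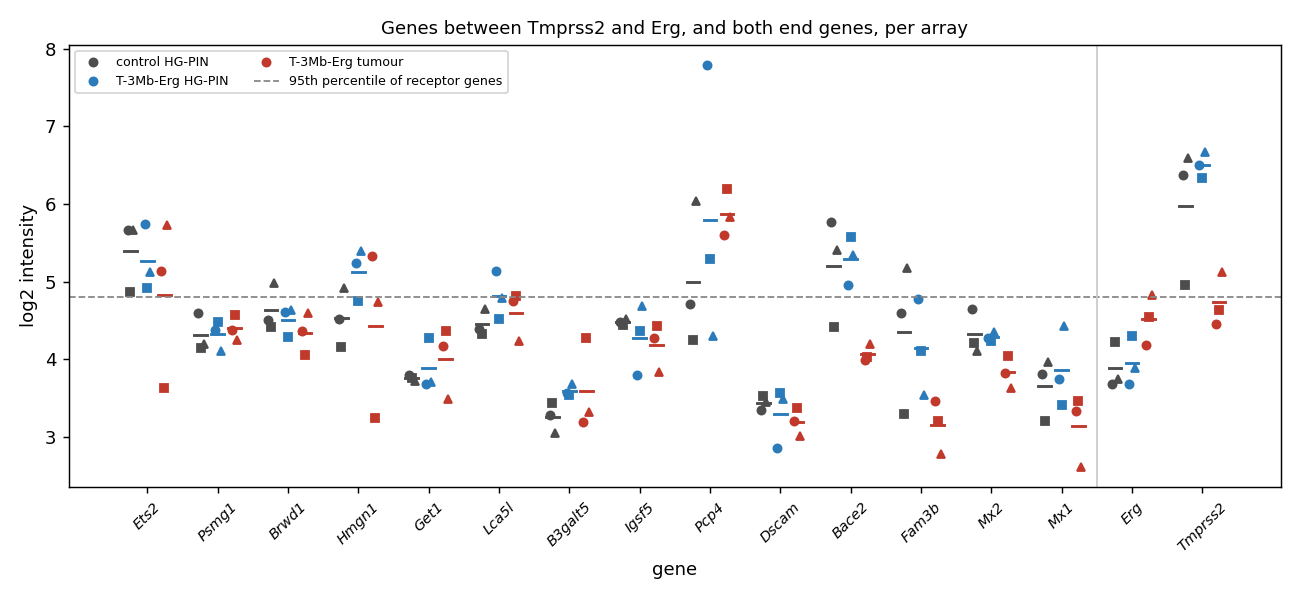
Log2 intensity (vertical axis) of the 14 tested interstitial genes and, right of the line, Erg and Tmprss2 on each array (horizontal axis, gene), with points for single arrays (circle, square and triangle for replicates 1, 2 and 3), short bars for group means of 3 arrays and a dashed line at 4.80, the 95th percentile of receptor genes. HG-PIN means of both genotypes lie close to each other for most genes, and 11 of the 14 interstitial genes have an average over all arrays below the dashed line.

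The end genes themselves did not differ between the HG-PIN groups by the test. Erg, another ETS-family factor, had log2 levels of 3.96 ± 0.32 in T-3Mb-Erg HG-PIN and 3.88 ± 0.29 in control HG-PIN (adjusted p = 0.998), below the receptor level in both. The labels do not give the Erg sequence the allele carries, so its probe set may not read the product of the allele. Tmprss2, an androgen-regulated serine protease, stood at 6.50 ± 0.16 and 5.97 ± 0.89 (change 0.53, adjusted p = 0.998).

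Across all 16635 genes, limma called 0 genes higher and 0 lower between the HG-PIN groups, with 304 higher and 378 lower at an unadjusted p under 0.05. Of the 16635, only 4647 (27.9%) had a mean above 4.80, the receptor level, so background may hide differences in most of them. The groups did not overlap for 10.1% of genes, where chance gives 10%. The named genes with the smallest p did not pass, with adjusted p values from 0.269 to 0.998. On the higher side they were Tlcd1 (2.30), Krt15, a basal keratin (1.98), Ppan, a ribosome biogenesis factor (2.51), AF357399, a small nucleolar RNA gene (1.94) and Gabrp, a GABA receptor subunit of epithelia (1.55), and on the lower side Hamp, the iron hormone hepcidin (-3.36), Tctn3 (-1.61), H2-M9 (-1.20), Snx16 (-0.94) and Ica1 (-0.71). With simulated changes, 28% of genes changed by 1 log2 unit and 100% of those changed by 2 were called in this comparison, against 11 false calls. The simulated noise was independent between genes and arrays and left out the differences in range between arrays. These shares may therefore overstate what the real arrays can detect, and Ppan at 2.51 and Hamp at -3.36 did not pass. A few genes passed under other settings: 4 on the 6 arrays of both groups alone, 9 with array weights and 6 with the range of each array as a term. Without the narrowest-range array of each group 4 passed, and leaving out single arrays gave 6 without tumour replicate 2 and 1 each without control HG-PIN replicate 3 or T-3Mb-Erg HG-PIN replicate 3. The range term and the fit without narrowest-range arrays were chosen after seeing the data.

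Of the 37 gene lists, 7 were higher in T-3Mb-Erg HG-PIN with the preset correlation and none held with an estimated one. The basal epithelial list had 15 of 18 members positive and a median change of 0.17 (adjusted p = 0.0115; adjusted p = 0.0519 with an estimated correlation). Krt15 passed when adjusted over the list alone, and Krt17 at 1.32 did not. Smooth muscle genes had 14 of 14 members positive and a median of 0.49 (adjusted p = 3.63e-06; adjusted p = 0.359 with an estimated correlation), with Tagln at 0.75 and Myl9 at 0.89, both contractile-apparatus genes. T-3Mb-Erg HG-PIN replicate 1 carried much of that list: its mean change went from 0.69 to 0.28 without that array. The score of the list (mean difference from the average of all arrays) was 1.23 on that array. It was 0.08 and -0.17 on T-3Mb-Erg HG-PIN replicates 2 and 3, and -0.35, -0.34 and -0.23 in control HG-PIN. The macrophage list had a median of 0.27 (adjusted p = 0.00589), interferon response 0.22 (0.00715), glycolysis and hypoxia 0.27 (0.00719), fibroblast 0.22 (0.0426) and cytosolic ribosome 0.33 (0.0314). All stood at adjusted p = 0.810 with an estimated correlation, and no member passed. The smooth muscle, macrophage and fibroblast lists hold markers of non-epithelial cells, which the captures may include. Whether their rises came from the epithelium or from such cells was not tested between the HG-PIN groups. Leaving out a single array ended the calls of the basal and macrophage lists (T-3Mb-Erg HG-PIN replicate 1, adjusted p = 0.0507 for both) and of the interferon list (control HG-PIN replicate 2, adjusted p = 0.236, or T-3Mb-Erg HG-PIN replicate 3, adjusted p = 0.133). The glycolysis call ended without control HG-PIN replicate 2 (adjusted p = 0.0543), and the fibroblast call without any 1 of 3 arrays (adjusted p up to 0.235). The ribosome call ended without T-3Mb-Erg HG-PIN replicate 1 (adjusted p = 0.176), and its mean went from 0.28 to -0.02 without control HG-PIN replicate 2. Other settings ended calls as well: with the range term the glycolysis, fibroblast and ribosome lists stood at adjusted p = 0.172, 0.248 and 0.248. Without the narrowest-range arrays the macrophage, interferon, glycolysis and ribosome lists stood at 0.0502, 0.889, 0.118 and 0.889. Of 21 settings, the smooth muscle call held in 21, the basal in 20, macrophage in 19, glycolysis in 18, interferon in 17, ribosome in 14 and fibroblast in 12. Single arrays moved means upward too, without control HG-PIN replicate 1 to 0.38 for interferon (from 0.24) and 0.50 for ribosome genes, and without T-3Mb-Erg HG-PIN replicate 3 to 0.68 for fibroblast (from 0.42) and 1.04 for smooth muscle genes. The other 30 lists did not pass, with medians from -0.91 for prostate secretory genes to 0.32 for epithelial-mesenchymal transition genes and a smallest adjusted p of 0.0607. The prostate secretory list, at a mean of -0.78 (adjusted p = 0.0607), passed in 7 of 21 settings, among them the range term (-1.04, adjusted p = 0.0134) and the fit without the narrowest-range arrays (-1.68, adjusted p = 8.91e-07), and stood at -0.12 (adjusted p = 0.826) without control HG-PIN replicate 3. The matrix remodelling list (mean 0.26, adjusted p = 0.0607) passed in 8 of the 21, with a mean between 0.14 and 0.46 and adjusted p = 0.00449 on the 6 arrays. The epithelial-mesenchymal transition, luminal epithelial and oxidative phosphorylation lists passed in 5 each, with means from 0.19 to 0.47, -0.06 to 0.37 and -0.10 to 0.34.

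The second comparison set poorly differentiated tumours against HG-PIN of the same 3 T-3Mb-Erg mice and addressed what distinguishes the tumour within an animal. Epithelial genes fell and mesenchymal genes rose in the tumours. Krt8, a luminal keratin, fell by 2.88 on the log2 scale (7.38-fold, adjusted p = 0.0154), the cell-cell adhesion molecules Cdh1 and Epcam fell by 2.88 and 2.55 (adjusted p = 0.0424 and 0.0430), and the tight junction protein gene Cldn4 fell by 3.76 (13.5-fold, adjusted p = 0.00436). Prrx1, a homeobox factor of mesenchyme, rose 7.32-fold (log2 change 2.87, SE 0.34, adjusted p = 0.00720), from 4.80 ± 0.52 in HG-PIN to 7.67 ± 0.46 in tumours (SD, n = 3 each). All these genes moved the same way in 3 of 3 mice. Tumour means of Cdh1, Epcam and Cldn4 were 4.76, 4.17 and 3.25, below the receptor level of 4.80, so the size of their falls is limited by background. With the mouse as a fixed replicate block Cldn4 kept its call (adjusted p = 0.0121), while Krt8, Cdh1, Epcam and Prrx1 stood at adjusted p = 0.0609, 0.0682, 0.0555 and 0.0572 and did not pass.

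In all, limma called 11 genes higher and 36 lower in tumours out of 16635, and 11.4% of genes had groups without overlap, where chance gives 10%. Besides Prrx1, the largest rises were in Ctla2a, a cysteine protease inhibitor (18.9-fold), Lox, the lysyl oxidase that crosslinks collagen (10.5-fold), Gja1, the gap junction protein connexin 43 (10.2-fold) and Gpx3, an extracellular glutathione peroxidase (7.90-fold). Smaller rises were in Gatm, an enzyme of creatine synthesis (5.47-fold), Slit3, a secreted guidance cue (4.64-fold), Spon2 (3.06-fold), Rtl8c (2.78-fold) and Arhgdib (2.63-fold). The largest falls were in Gsdmc2, a gasdermin (42.4-fold), the antimicrobial lectins Reg3b and Reg3g (31.9-fold and 23.0-fold), Mmp7, an epithelial metalloproteinase (29.9-fold), and Slc12a2, a chloride cotransporter (25.9-fold). They were followed by Cbr2, a carbonyl reductase (18.7-fold), Cxcl15 (17.3-fold), Pigr, which carries antibodies across epithelia (15.3-fold), and Tspan1 (12.7-fold), with adjusted p values from 0.00400 to 0.0458. With the fixed block 20 of the 47 called genes kept their call, with Ctla2a (adjusted p = 0.0359) the only member of the 11 higher ones. Of the lower genes named here, all but Reg3b (adjusted p = 0.0609) passed. Folds in both directions are limited by background: the HG-PIN mean of 8 of these 10 higher genes and the tumour mean of 8 of the 10 largest falls lay at or below 4.80, down to 3.19 for Gatm and 2.15 for Reg3g.

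**Figure D2:**
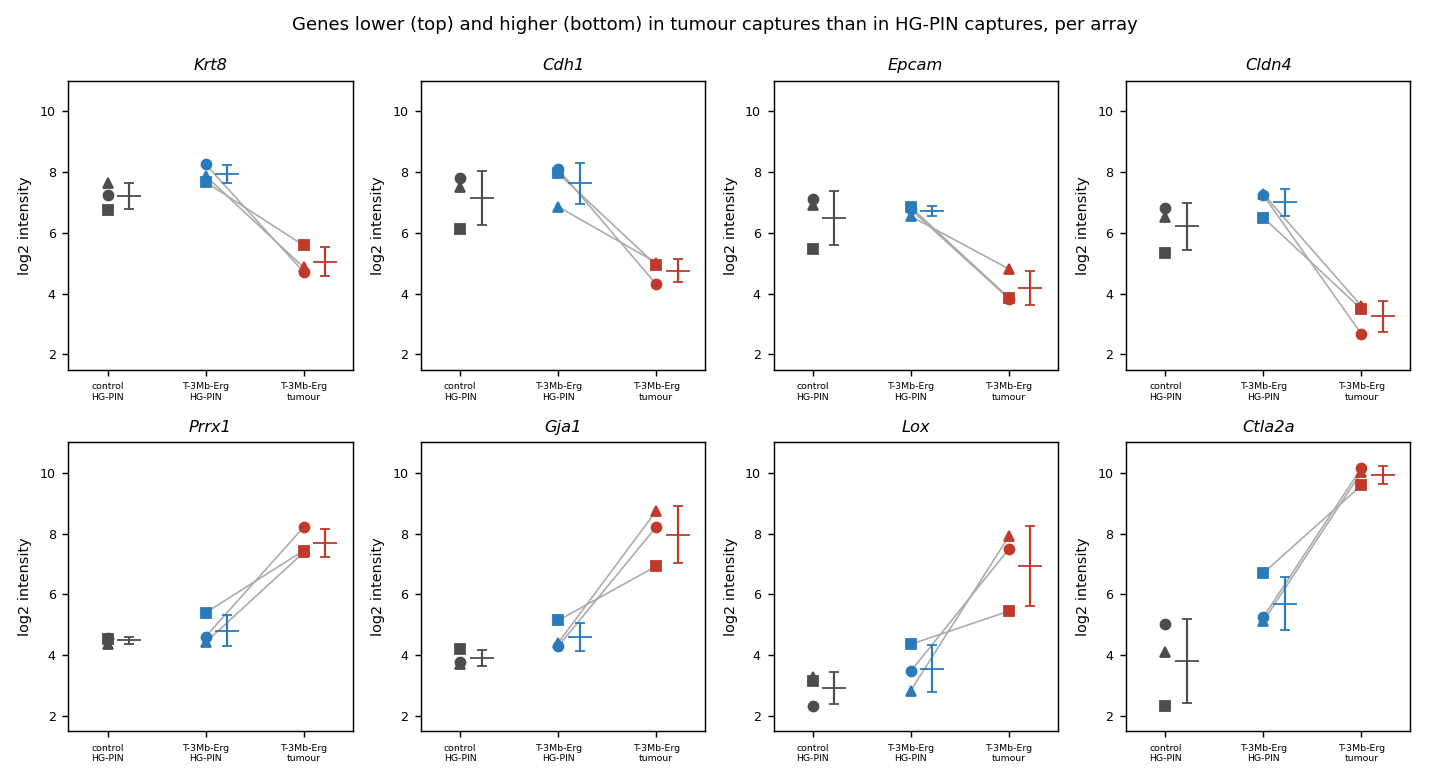
Log2 intensity (vertical axis, same scale in all panels) of Krt8, Cdh1, Epcam and Cldn4 (top) and Prrx1, Gja1, Lox and Ctla2a (bottom) in the 3 groups (horizontal axis), with a point per array, the mean and SD of 3 arrays beside them and grey lines joining HG-PIN and tumour of the same mouse. Every line falls in the top row and rises in the bottom row, as in Ctla2a from 5.69 ± 0.88 to 9.93 ± 0.30.

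All 25 tested luminal epithelial genes were lower in tumours, with a median change of -1.39 (2.62-fold; adjusted p = 1.18e-30, and adjusted p = 1.11e-04 with an estimated correlation). The tumour means of 19 lay below 4.80, so the sizes of these falls, too, are limited by background. Of the list, 9 fell by the test over all genes and 20 when adjusted over the list alone. They included Elf3 (-2.91), Ehf (-2.62) and Foxa1 (-2.74), transcription factors of epithelia, and St14, a membrane serine protease (-1.88). Krt18, the partner of Krt8, stood at -1.35 and did not pass (adjusted p = 0.623). Basal epithelial genes had 14 of 18 members negative and a median of -0.34 (adjusted p = 5.31e-05; 1.77e-04 with an estimated correlation), and Krt15 fell by 3.00 (adjusted p = 0.0572 with the fixed block), while Krt14 at -1.41 did not pass (adjusted p = 0.0955). All 12 prostate secretory genes were negative, with a median of -1.70 (adjusted p = 5.85e-07; adjusted p = 0.121 with an estimated correlation), of which Pigr passed. Tmprss2 stood at 4.74 ± 0.35 in tumours against 6.50 ± 0.16 in HG-PIN and did not pass over all genes (log2 change -1.77, adjusted p = 0.141). With Erg it forms the engineered list, in which both genes passed when adjusted over the list alone.

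Epithelial-mesenchymal transition genes had 12 of 15 members positive and a median of 1.06 (adjusted p = 1.64e-08; 0.00669 with an estimated correlation). Prrx1 passed over all genes and 8 genes passed when adjusted over the list alone, among them Snai2, a repressor of E-cadherin (1.33), Tgfbi (2.76) and Vim, the filament protein of mesenchymal cells (1.80, adjusted p = 0.256 over all genes). Fibroblast markers rose with them: 20 of 20 were positive, with a median of 0.93 (adjusted p = 4.67e-10; 0.0467 with an estimated correlation), none passed over all genes, and 8 passed when adjusted over the list alone, with Pdgfra at 1.95 and Col1a1 at 1.68. In the 3 mice, the mean difference of the fibroblast list between tumour and HG-PIN was 0.85, 0.01 and 2.29, the smallest in the mouse of tumour replicate 2, whose array had the narrowest range of the tumours. That of the luminal list was -1.90, -1.63 and -1.38. The transition list gave 1.14, 0.27 and 1.79, which ranks the 3 mice as the fibroblast list does. Without tumour replicate 3 the fibroblast mean went from 1.05 to 0.51 (adjusted p = 0.00242). Matrix remodelling genes had 21 of 23 members positive and a median of 0.83 (adjusted p = 3.26e-09; adjusted p = 0.0643 with an estimated correlation). Lox rose and Mmp7 fell, and the mean went from 0.67 to 0.29 without tumour replicate 3. The 3 mice gave 0.62, -0.16 and 1.55, so the matrix list fell in 1 of them. TGF-beta pathway genes had a median of 0.28 (adjusted p = 3.12e-04; 0.00106 with an estimated correlation), with 5 of 19 higher when adjusted over the list alone, among them the ligand genes Tgfb1 (1.06), Tgfb3 (1.22) and Inhba (1.05).

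**Figure D3:**
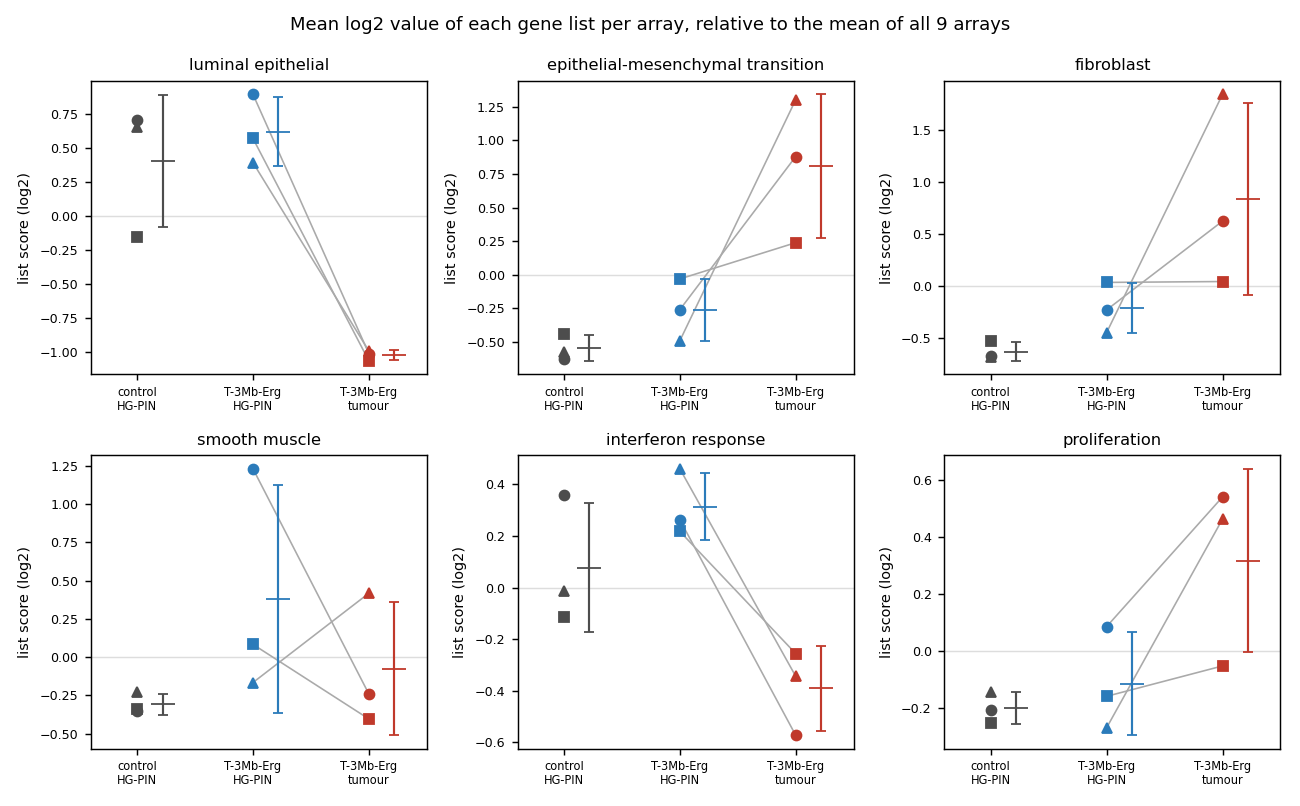
Score of 6 gene lists on each array (vertical axis, mean over the list of the log2 difference from the average of the 9 arrays) in the 3 groups (horizontal axis), with points per array, mean and SD of 3 arrays, and grey lines joining captures of the same mouse. The luminal epithelial list averages 0.62 ± 0.25 in T-3Mb-Erg HG-PIN and -1.02 ± 0.04 in tumours, and the fibroblast list rises steeply in 1 mouse and hardly in another.

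Interferon response genes fell as a group, with 29 of 30 members negative and a median of -0.65 (adjusted p = 7.72e-14, and 0.00669 with an estimated correlation). None passed over all genes, 8 passed when adjusted over the list alone, and Oasl2 (-2.47), Oas2 (-1.62) and Irf7 (-1.31) were among them. The tumour means of 20 of the 29 lay below 4.80, so background limits the size of this fall. Proliferation genes had 30 of 39 members positive and a median of 0.27 (adjusted p = 2.18e-06; 0.0485 with an estimated correlation), with no member past the threshold and Mki67 at 0.78 (adjusted p = 0.806). HG-PIN means lay below 4.80 for 27 of these 30, as for 12 of the 20 fibroblast and 16 of the 21 matrix genes that rose. The interstitial genes had 10 of 14 negative, with a median of -0.19 (adjusted p = 0.0146; adjusted p = 0.104 with an estimated correlation). None passed, with Bace2 (-1.21, adjusted p = 0.251), Fam3b (3.15 ± 0.34 against 4.14 ± 0.62) and Mx1 (-0.72) at an unadjusted p under 0.05. Mx1 and Mx2 are also members of the interferon list. Without tumour replicate 3 or T-3Mb-Erg HG-PIN replicate 1 the interstitial list no longer passed (adjusted p = 0.108 and 0.0960). Erg stood at 4.52 ± 0.32 in tumours and 3.96 ± 0.32 in HG-PIN (change 0.56, adjusted p = 0.628). ERG-associated genes had a median of 0.20 (adjusted p = 3.79e-04; adjusted p = 0.0518 with an estimated correlation, and 0.0574 with the preset one without tumour replicate 3), of which Arhgdib rose. Their mean went from 0.36 to 0.18 without that array, and the 3 mice gave 0.19, 0.07 and 0.82. Endothelial markers had a median of 0.27 (adjusted p = 9.86e-05; adjusted p = 0.264 with an estimated correlation), smooth muscle genes -0.40 (0.0146; adjusted p = 0.577 with an estimated correlation) and oxidative phosphorylation genes -0.22 (0.0392; adjusted p = 0.848 with an estimated correlation). The endothelial mean went from 0.36 to 0.20 without tumour replicate 3, and its call ended with array weights (adjusted p = 0.125), as did the smooth muscle call (0.128). The smooth muscle call ended without tumour replicate 2 or T-3Mb-Erg HG-PIN replicate 1 (means -0.26 and -0.05 against -0.46, adjusted p = 0.356 and 0.747), and its mean was -0.81 without T-3Mb-Erg HG-PIN replicate 3. The 3 mice gave -1.47, -0.49 and 0.58, so the sign was opposite in 1 of them. The oxidative phosphorylation call ended without tumour replicate 2 or T-3Mb-Erg HG-PIN replicate 1, with a mean of 0.08 and -0.02 against -0.22, as well as with array weights (0.880) and without the narrowest-range arrays (0.779).

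The remaining 23 lists did not pass in tumours against HG-PIN, with medians from -1.18 for seminal vesicle genes to 0.12 for red blood cell genes and a smallest adjusted p of 0.0657. Median and mean differed in sign for 7 of them. Single members passed in the macrophage list (Cd14, a receptor for bacterial lipopolysaccharide that epithelia also express, -1.73, adjusted p = 0.0409) and in the seminal vesicle list (Gpx3). With the mouse as a fixed replicate block on the 6 arrays, 1 gene was higher and 25 lower, the 14 list calls held, and the seminal vesicle list passed as well (adjusted p = 0.0155, against 0.152). Cd14 did not pass with that block (adjusted p = 0.0683). The count rested on single arrays: 0 genes passed without tumour replicate 1, 5 without T-3Mb-Erg HG-PIN replicate 1, 8 without its replicate 2 and 21 without control HG-PIN replicate 3. It rose to 76 without control HG-PIN replicate 2, 94 without tumour replicate 3, 99 without T-3Mb-Erg HG-PIN replicate 3 and 110 without tumour replicate 2.

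The third comparison set tumours of T-3Mb-Erg mice against HG-PIN of control mice, where genotype and lesion both differ. Ctla2a rose 69.6-fold, from 3.81 ± 1.37 to 9.93 ± 0.30 (log2 change 6.12, SE 0.63, adjusted p = 0.00525), and Gja1, Lox, Prrx1 and Slit3 rose 16.7-fold, 16.4-fold, 9.15-fold and 6.93-fold. Further rises were in Lgals1, a galectin (14.7-fold), Serping1, an inhibitor of complement C1 (13.4-fold), Slc43a3 (7.19-fold), Gpx3 (6.64-fold) and Lrp1, an endocytic receptor (6.45-fold). Mmp7, Cbr2, Clu, a secreted chaperone (10.5-fold), Cldn4, Cyp2f2, Foxa1, Myo5c, Car2, Ltf, the iron-binding lactoferrin, and Egf, the epidermal growth factor precursor, fell, by 21.4-fold for Mmp7 down to 4.09-fold for Egf (adjusted p from 0.0161 to 0.0486). Folds are limited by background here too: the control HG-PIN mean of 9 of these 10 higher genes and the tumour mean of 8 of these 10 lower ones lay below 4.80, down to 2.91 for Lox and 3.09 for Egf. In all, limma called 18 genes higher and 12 lower, and 13.7% of genes had groups without overlap, where chance gives 10%.

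All 25 luminal epithelial genes were again negative in this comparison, with a median of -1.21 (adjusted p = 9.75e-24; 6.32e-04 with an estimated correlation), 3 called over all genes (Cldn4, Foxa1 and Rab25) and 19 when adjusted over the list alone. Prostate secretory genes had 11 of 12 negative and a median of -2.53 (adjusted p = 2.47e-10; 0.0438 with an estimated correlation). None passed over all genes, and 9 passed when adjusted over the list alone, with the defensin gene Defb50 at -5.00. Epithelial-mesenchymal transition (15 of 15 positive, median 0.97), fibroblast (19 of 20, 1.16), matrix remodelling (22 of 23, 1.06) and TGF-beta pathway genes (16 of 19, 0.40) rose as groups. Their adjusted p values were 6.32e-04, 0.0169, 0.0292 and 4.95e-05 with an estimated correlation. Of these lists, Prrx1 and Lox rose and Mmp7 fell over all genes, and 8, 11, 11 and 4 members were higher when adjusted over the list alone. Control HG-PIN means lay below 4.80 for 11 of the 15, 14 of the 19, 17 of the 22 and 13 of the 16 members that rose. The fibroblast and matrix means went from 1.47 to 0.93 and from 0.93 to 0.55 without tumour replicate 3. Proliferation genes (35 of 39 positive, median 0.30, adjusted p = 0.0185 with an estimated correlation) rose as a group too, with Rrm2, a subunit of ribonucleotide reductase, at 3.58 (adjusted p = 0.110). So did ERG-associated genes (17 of 24, 0.42, adjusted p = 0.0438 with an estimated correlation), of which Arhgdib rose, their mean going from 0.39 to 0.21 without tumour replicate 3.

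Calls of 4 further lists were lost with an estimated correlation: interferon response (median -0.49, adjusted p = 1.39e-06 and then 0.105), endothelial (0.26, adjusted p = 1.03e-05 and then 0.188; Pecam1 at 1.28), glycolysis and hypoxia (0.42, adjusted p = 0.00116 and then 0.371) and inflammatory genes (-0.30, adjusted p = 0.0475 and then 0.104). Without tumour replicate 3 the glycolysis list no longer passed (adjusted p = 0.244) and the endothelial mean went from 0.46 to 0.31. The inflammatory list no longer passed without any 1 of 5 arrays (adjusted p up to 0.139), and with the range term neither it nor the glycolysis list passed (adjusted p = 0.0658 for both). Interstitial genes had 9 of 14 negative and a median of -0.27 (adjusted p = 0.195), with Bace2 at -1.13 and Fam3b at -1.21. Their mean, -0.23, ranged from -0.12 to -0.38 and passed in 2 of 21 settings, without the narrowest-range arrays (-0.38, adjusted p = 0.0335) and without control HG-PIN replicate 2 (-0.38, adjusted p = 0.0114). Erg stood at 0.64 (adjusted p = 0.419) and Tmprss2 at -1.23 (adjusted p = 0.316). The other 25 lists had medians from -1.05 to 0.25 and a smallest adjusted p of 0.125. The count rested on single arrays here as well: 0 genes passed without control HG-PIN replicate 3, 1 without its replicate 1, 3 without tumour replicate 1, 7 without tumour replicate 3 and 6 without T-3Mb-Erg HG-PIN replicate 3. There were 20 without either other T-3Mb-Erg HG-PIN array, 88 without control HG-PIN replicate 2 and 261 without tumour replicate 2. On the 6 arrays of the 2 groups alone, 6 genes were higher and 1 lower.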

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

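The tests on probe sets without a gene name were chosen only after the results of the named genes were seen. Of 10343 tested probe sets without a single gene name, 1 was lower in T-3Mb-Erg tumours than in HG-PIN of the same mice (log2 change -3.86, adjusted p = 0.0264), and 1 was higher in tumours than in control HG-PIN (4.49, adjusted p = 0.0287). What they measure was not analysed here. Between the HG-PIN groups none passed.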

How the results depend on the processing

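The alternatives were set before the data were examined, except the fit without the lowest-range array of each group and the fit with each array's 95th percentile as a term, chosen only after the result was seen. For genes higher and lower in T-3Mb-Erg HG-PIN than in control HG-PIN, 0 and 0 became 2 and 2 on the 6 arrays of both groups, 8 and 1 with array weights, 3 and 1 without the lowest-range arrays (fitted as independent arrays) and 6 and 0 with the range term. Leaving out single arrays gave 0 to 4 higher and 0 to 2 lower.

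For tumours against HG-PIN of the same mice, 11 higher and 36 lower became 39 and 67 at an adjusted p under 0.10, 17 and 46 in the upper signal range, 7 and 45 on the 6 arrays, 24 and 48 with quantile normalization, 226 and 179 with array weights, 83 and 99 without the lowest-range arrays and 59 and 121 with the range term. A fixed replicate block left 1 higher and 25 lower, with 20 of the 47 kept. Single arrays left out gave 0 to 85 higher and 0 to 84 lower. For tumours against control HG-PIN, 18 and 12 became 64 and 44 at 0.10, 6 and 1 on the 6 arrays, 36 and 29 with quantile normalization, 515 and 423 with array weights, 143 and 117 without the lowest-range arrays and 80 and 91 with the range term. Single arrays left out gave 0 to 216 higher and 0 to 70 lower. Every called gene kept its sign in every setting.

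The interstitial median in tumours against HG-PIN, -0.19, lost its call with an estimated correlation (adjusted p = 0.104), with fry (0.159) and with array weights (-0.11), and lay between -0.33 and -0.19 without single arrays. Of the lists called in a comparison, 2 turned direction, and means of lists without a call changed sign more often. Cytosolic ribosome genes between the HG-PIN groups ranged from -0.0242 without control HG-PIN replicate 2 to 0.50 without replicate 1. Oxidative phosphorylation genes in tumours against HG-PIN reached 0.0180 with array weights, ranged from -0.43 without tumour replicate 3 to 0.0806 without tumour replicate 2, and stood at -0.0164 without T-3Mb-Erg HG-PIN replicate 1. Against control HG-PIN, where they were not called, they ranged from -0.32 without control HG-PIN replicate 2 to 0.25 without tumour replicate 2. The cause was not tested.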

Other observations

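The tests in this part on small nucleolar RNAs, on cell types within mice and on signal near background were chosen only after the result was seen. Small nucleolar RNAs, which guide modification of ribosomal RNA, were higher in T-3Mb-Erg HG-PIN than in control HG-PIN as a group. Of 70 with a Snor or Scarna symbol, 63 were positive, with a median log2 change of 1.15, and 0 passed in the main fit. Some passed in other settings, such as Snord19 on the 6 arrays (adjusted p = 0.00199), with array weights (0.0119) and with the range term (0.0192). Snord70 (3.66), Snord19 (3.62) and Snord1b (3.11) had the largest values. The median level was 5.40 ± 0.35 in control HG-PIN, 6.97 ± 0.03 in T-3Mb-Erg HG-PIN and 6.24 ± 0.23 in tumours (SD, n = 3 each). Snord123 rose in tumours against control HG-PIN (4.98, adjusted p = 0.0138).

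Single genes passed over their list alone in lists that did not pass as a whole, and were chosen after their values were seen. Fads1, a fatty acid desaturase, had a log2 change of 1.68 in tumours against HG-PIN and 2.14 against control HG-PIN, and Ncam1, a neural adhesion molecule, 1.75 and 1.63. Both passed when adjusted over the list alone and not over all genes, and other members of their lists had changes of the opposite sign, such as Acss2 (-0.76) and Sox2 (-1.29) in tumours against HG-PIN. Lcn2, an iron-binding protein of neutrophils and inflamed epithelia, stood at -2.44 and -2.37 and passed over its list alone.

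The loss of epithelial and gain of mesenchymal genes in tumours could come from the carcinoma cells or from other cells in the captures. A general rise of non-epithelial cells predicts that fibroblast genes rise like smooth muscle, endothelial and macrophage genes. The mean fibroblast change exceeded that of smooth muscle by 1.51 ± 0.93 and that of macrophages by 1.17 ± 0.95 (SD, 3 mice), but that of endothelium by 0.69 ± 0.92 with mixed signs, so this remains open. More fibroblasts alone remain open too: in 1 of 3 mice the fibroblast list rose by less than 0.1 while the luminal list fell by 1.63. The dynamic range of the arrays is argued against, as the luminal median stayed at -1.44 with the range term.

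For the small nucleolar RNAs, transcription of their host genes predicts a similar rise there, and the host genes had a median of 0.20, which argues against it. The range is argued against as well, since the median was 1.15 with the range term. Recovery or amplification of short RNAs in general remains open: the median was 0.48 over 9 other short non-coding RNAs (bootstrap 95% interval 0.15 to 1.53), with Rny1 at 1.53 and Rn7sk at 0.22. An unrecorded processing batch and the genotype could not be told apart, as the groups differ in both if batches followed them.

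For the interstitial genes, signal near background may hide a lower transcript level, and this remains open with 3 of 14 genes above the receptor level. The number of called genes was set against the 10 splits of each 6 arrays, which cannot give a share under 0.05. Between the HG-PIN groups 0 genes were called, which all 10 splits reach whatever their values (highest 2), so the splits decide nothing there. For tumours against HG-PIN 1 split, the real one, reached 47 (highest other 1), and for tumours against control HG-PIN 1 reached 30 (highest other 0).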
